A study of Homo sapiens with 20 samples.

How the data were processed

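Per the labels, the drug arm was deposited by the authors as STAR gene counts and the excision arm as kallisto transcript tables with estimated counts and TPM, both against hg19, from stranded total RNA libraries with rRNA removed. The authors' labels name Trimmomatic 0.38, STAR 2.7.3a and kallisto 0.44.0, and do not state an annotation release. In the drug arm the reverse strand column of the counts was used, since it held 8.01 to 9.77 times the forward column. In the excision arm estimated counts were summed per gene and rounded. Of 215170 transcript identifiers 182238 (84.7%) were found in GENCODE 29, giving 53153 genes that hold 87.8% to 90.4% of the estimated counts. The drug tables hold 57736 gene identifiers, 52301 of them in GENCODE 29. GENCODE 29 is built on GRCh38, so it served for names, gene types, GC content and gene order, and no coordinates were used.

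Each arm was fitted by itself, with all its groups in a model with one mean per group, in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors (0.873 to 1.09 in the drug arm, 0.955 to 1.05 in the excision arm) and the robust quasi-likelihood test. The p values were adjusted by Benjamini-Hochberg over all tested genes, 19224 in the drug arm and 21285 in the excision arm, and 0.05 was the threshold. The biological coefficient of variation was 0.129 with 6 residual degrees of freedom in the drug arm and 0.323 with 4 in the excision arm. An exact permutation test of 2 against 2 libraries cannot give a p under 0.333, so every p rests on the variance model. Standard errors were derived as the absolute fitted log2 fold change over the square root of the quasi-likelihood F statistic, so they are approximate. A gene with 0 counts in a group is given as at least so many fold, against a floor of 3 counts over the group, and one with 1 to 3 counts as a ratio with its 95% counting interval, because the fitted fold of such a gene is no bound.

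The gene lists were written from general knowledge of the genes before the data were examined, as were the comparisons, the thresholds, the rule for named genes and all alternatives not said below to be added. The 30 lists cover PRC2, REST corepressors, REST target genes of neurons, HOX genes, Polycomb-repressed developmental transcription factors, FGF18 with its neighbours on 5q35.1 (the silencer locus), globins, erythroid, megakaryocytic, myeloid, lymphoid, and fibroblast and epithelial markers, mitosis, DNA replication, cell cycle arrest, apoptosis, ATF4 targets, endoplasmic reticulum chaperones, oxidative stress targets, heat shock, cholesterol synthesis and uptake, metallothioneins with zinc exporters, hypoxia, interferon, antigen presentation, adhesion, FGF signalling, ribosome biogenesis, mitochondrial genome mRNAs and histones. Lists with at least 5 tested genes went to camera (limma 3.58.1) with a preset correlation of 0.01, then with an estimated correlation, and to fry. Of 290 tests in the drug arm 128 passed with the preset and 2 with an estimated correlation, and of 180 in the excision arm 59 and 0. Mitochondrial genome mRNAs were not tested in the drug arm. Histone names matched for 21 of 36 genes and DNA replication names for 29 of 30.

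Named genes are the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 2 CPM and separate replicates in the GSK343, X5050, 72 h and DKO comparisons with their controls, 4 and 4 in the others, the targets EZH2, REST and FGF18, and up to 4 called members of each list with the lowest p. From these, genes whose call stood with any 1 library left out were preferred in the text, a choice made after the values were seen. Of the named calls that held so, there were 44 of 105 for GSK343, 54 of 102 for X5050, 112 of 128 for both drugs at 72 h, 20 of 38 for S1KO, 11 of 29 for S2KO and 40 of 76 for DKO.

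Alternatives were DESeq2 1.42.0, RLE size factors, no filter beyond 1 count, a replicate block, unstranded counts or length-scaled TPM counts, only the groups compared, and each library left out. Added after the data were seen were fits with only the 72 h groups, fits without the DKO libraries, and fits with the GC trend removed by a loess of span 0.3 on the GC content of the longest transcript. GC content was known for 96.2% of tested genes in the drug arm. The code was tested on simulated data with 200 genes changed. In the 72 h design it recovered 53 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, with 8 of the unchanged genes called. In the DKO design it recovered 2 and 32 of 100, with 1 unchanged gene called, so changes of 4-fold or less are mostly missed there. With a GC trend simulated at 8 h, 2939 unchanged genes were called with the trend kept and 1 with it removed. Overlaps between comparisons with shared controls were set against 10 simulated draws of unchanged groups and, a test added after the data were seen, against covariances with a separate control library for each comparison. Those without shared libraries were tested by Fisher's exact test. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for tables and figures. Transcript-level changes, the deposited TPM as such and reads outside annotated genes were left out. Some genes withheld for evaluation are not reported here.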

Results

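The series holds RNA-seq of K562, a human erythroleukemia line, in 20 libraries of 10 groups with n = 2 libraries each. The drug arm has 12 libraries of 22925617 to 38177320 gene counts. Cells received DMSO, the EZH2 inhibitor GSK343 (5 uM) or the REST inhibitor X5050 (100 uM) for 72 h. Both drugs at these doses ran for 8, 24 or 72 h. In the excision arm (8 libraries, 55913728 to 98507880 gene-level estimated counts) silencer 1 (S1KO), silencer 2 (S2KO) or both (DKO) were removed by CRISPR and compared with an empty vector (EV). Values after ± are standard errors of log2 fold changes or standard deviations of CPM, counts scaled to library size. The genes singled out as risen or fallen had both libraries of one group beyond both of the other.

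Does FGF18, the growth factor gene the silencers act on, come up when the silencers or their repressors are removed? FGF18 was close to silent throughout. It had 1 and 4 counts in the DMSO libraries, 7 and 12 with GSK343, 3 and 1 with X5050, and 33 and 25 (1.45 and 0.954 CPM) after 72 h of both drugs. The rise with both drugs was 11.6-fold (counting interval 4.71 to 37.2; log2 3.50 ± 0.68, edgeR adjusted p = 0.000808), and its level was also above that of X5050 alone by log2 4.01 ± 0.70 (adjusted p = 0.000478). It was above that of GSK343 alone by 1.93 ± 0.56 (0.0122), a call lost without replicate 1 of both drugs (0.120) or GSK343 replicate 1 (0.1002), and with DESeq2 (0.0677). GSK343 alone gave log2 1.58 ± 0.77 (adjusted p = 0.205), X5050 alone -0.51 ± 0.98 (0.799), and both drugs 0.66 ± 0.82 at 8 h (0.544) and 1.78 ± 0.75 at 24 h (0.0676). The test of whether both drugs gave more than the single drugs add up to did not pass for FGF18 (log2 2.43, adjusted p = 0.161).

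In the excision arm FGF18 had 9 and 0 counts in EV, 6 and 1 in S1KO, 9 and 2 in S2KO, and 16 and 16 (0.274 and 0.259 CPM) in DKO. The DKO to EV ratio was 4.81 (counting interval 2.24 to 11.5), but the edgeR test did not pass (log2 2.21 ± 1.28, adjusted p = 0.350), nor did S1KO (-0.61 ± 1.43, 0.915) or S2KO (0.34 ± 1.36, 0.992). These intervals cover counting error alone. With EV replicate 1 left out the DKO log2 value was 7.39, and the S1KO value turned to 4.57, because the other EV library has 0 counts; without EV replicate 2 the DKO value was 1.21 and the S1KO value -1.61.

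**Figure D1:**
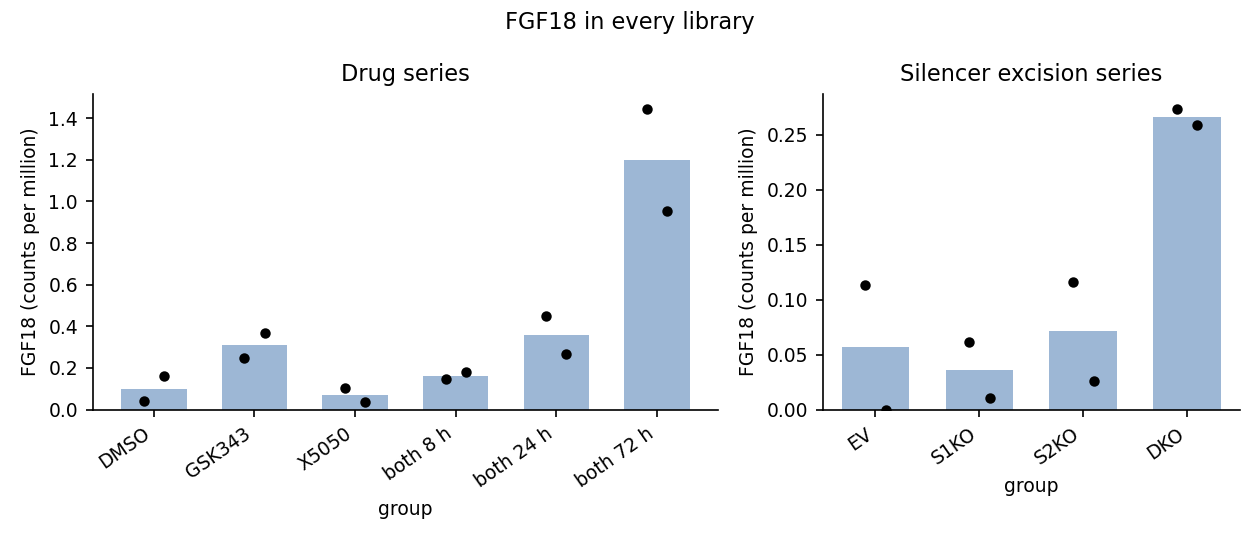
FGF18 in CPM in each library of the drug series and of the excision series. Bars give group means and points single libraries (n = 2 per group).

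Transcripts of the drug targets moved little at 72 h. EZH2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2), had log2 -0.15 ± 0.13 with GSK343 (edgeR adjusted p = 0.514) and -0.18 ± 0.13 with X5050 (0.433). REST, the repressor of neuronal genes, had 0.11 ± 0.13 (0.667) and 0.34 ± 0.13 (0.103). With both drugs REST was above 72 h DMSO at 8 h (0.92 ± 0.13, adjusted p = 4.51e-05) and 24 h (0.98 ± 0.13, 2.38e-05), and had 0.19 ± 0.13 at 72 h (0.277). EZH2 had -0.38 ± 0.13 at 72 h of both drugs (adjusted p = 0.0354), a call lost without DMSO replicate 1 (0.323) or replicate 1 (0.153) or 2 (0.111) of both drugs, and with the GC trend removed (0.192). EZH2 rose at 24 h (0.79 ± 0.13, adjusted p = 0.000198) and was lower at 72 h than at 24 h (-1.17 ± 0.14, 5.36e-06). In the excision arm EZH2 had 0.03 ± 0.17 in S1KO, 0.25 ± 0.17 in S2KO and -0.17 ± 0.17 in DKO, and REST had 0.21, 0.03 and 0.05 (each ± 0.14), with no call.

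What did the EZH2 inhibitor GSK343 do? Its largest changes were rises. SLFN11, a helicase that blocks stressed replication forks, rose from 0.123 ± 0.0602 to 6.25 ± 0.328 CPM (log2 5.63 ± 0.40, edgeR adjusted p = 4.73e-07), and the phosphatase-like gene PALD1 from 0.183 ± 0.0247 to 9.04 ± 0.216 (5.60 ± 0.34, 1.47e-07). CYP4F2, a fatty acid hydroxylase (5.62 ± 0.55), OLAH, a thioesterase (5.35 ± 0.48), and the early growth response factors EGR3 (5.58 ± 0.52) and EGR2 (4.96 ± 0.51) followed, all with adjusted p at or below 1.45e-05. Falls were smaller. FAXDC2 (-1.23 ± 0.22, adjusted p = 0.00254) and ADTRP (-1.19 ± 0.20, 0.00112) were among those that stood with any library left out. Of 2390 genes called, 1754 rose and 636 fell, and of those beyond 1 log2 unit 1199 rose and 38 fell. Without DMSO replicate 1 the split was nearer to even, with 2321 up and 1966 down.

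Genes of neuronal and developmental programs rose as groups with GSK343. Of 29 measured REST target genes of neurons 11 rose and 0 fell, or 18 and 0 when p was adjusted over the list alone (median log2 0.95). This list passed camera with the preset correlation (adjusted p = 4.02e-06) and also with adjusted p = 0.0395 with an estimated correlation. CALB1, a calcium buffer, rose from 9.35 ± 0.0370 to 26.5 ± 1.62 CPM (adjusted p = 1.84e-05) and TMEM59L by log2 2.28 ± 0.41 (0.00186). Of 21 Polycomb-repressed developmental transcription factors 6 rose and 0 fell (11 and 0 over the list alone, median 0.66, camera adjusted p = 0.000181, but adjusted p = 0.0584 with an estimated correlation). PAX5, the B cell factor, was among them (3.18 ± 0.42, adjusted p = 0.000134). The 17 measured HOX genes did not pass (1 up and 0 down, 2 and 1 over the list alone, median 0.01, mean 0.45, camera adjusted p = 0.678). Among 9 genes of the silencer locus on 5q35.1, 4 rose (4 over the list alone, median 0.60, camera adjusted p = 0.00187, but adjusted p = 0.238 with an estimated correlation). The podosome adaptor gene SH3PXD2B was at 2.59 ± 0.24 (5.68e-06) and UBTD2 at 2.00 ± 0.29 (0.000305). The camera call of that list was lost without DMSO replicate 1 (adjusted p = 0.117).

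Surface and growth factor signalling genes also rose with GSK343. Of 24 adhesion genes 10 rose and 0 fell (13 and 0 over the list alone, median 0.58, camera adjusted p = 4.02e-06, adjusted p = 0.171 with an estimated correlation). The hyaluronan receptor gene CD44 went from 1.02 ± 0.0347 to 10.5 ± 0.485 CPM (log2 3.36 ± 0.35, edgeR adjusted p = 3.58e-05), with ITGB2 (3.54 ± 0.44, 8.37e-05), EPHB6 (2.72 ± 0.23, 1.33e-05) and ITGB5 (1.21 ± 0.14, 2.90e-05). Of 18 FGF signalling genes 6 rose and 0 fell (7 and 0 over the list alone, median 0.28, camera adjusted p = 0.000174, adjusted p = 0.0584 with an estimated correlation). They included the feedback inhibitors SPRY4, from 31.6 ± 3.47 to 127 ± 12.8 CPM (4.73e-07), DUSP5 (1.59 ± 0.20, 0.000128) and DUSP4 (2.24 ± 0.31, 0.000214), and the receptor gene FGFR1 (2.82 ± 0.42, 0.000362). Megakaryocytic genes rose (4 up and 1 down of 14, 5 and 1 over the list alone, median 0.82, camera adjusted p = 0.00800, adjusted p = 0.155 with an estimated correlation). The collagen receptor gene GP6 was at 2.26 ± 0.23 (1.12e-05) and the integrin gene ITGA2B at 1.42 ± 0.19 (0.000149). Antigen presentation genes (5 up and 0 down of 15, 6 and 0 over the list alone, median 0.33, mean 0.90) had a camera adjusted p = 0.0163, and adjusted p = 0.373 with an estimated correlation. HLA-B rose by 2.62 ± 0.40 (0.000661), and the call of the list was lost without DMSO replicate 1 (0.188) or GSK343 replicate 2 (0.166).

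Erythroid and dividing-cell genes were lower with GSK343. All 30 mitosis genes were measured, and 15 fell and 0 rose (26 and 0 over the list alone, median log2 -0.39, camera adjusted p = 8.74e-13, but adjusted p = 0.275 with an estimated correlation). DNA replication genes fell (10 down and 0 up of 29, 12 and 0 over the list alone, median -0.25, camera adjusted p = 7.74e-09, adjusted p = 0.317 with an estimated correlation), among them the origin factors ORC1 (-0.68 ± 0.11, edgeR adjusted p = 0.00103) and CDT1 (-0.56 ± 0.11, 0.00350) and the thymidine kinase gene TK1 (-0.58 ± 0.12, 0.00390). The 16 histone genes had 6 down and 0 up (7 over the list alone, median -0.38, camera adjusted p = 6.48e-06, adjusted p = 0.317 with an estimated correlation). Erythroid genes fell (6 down and 0 up of 32, 15 and 0 over the list alone, median -0.48, camera adjusted p = 7.74e-09, adjusted p = 0.317 with an estimated correlation). The mitochondrial iron importer gene SLC25A37 was at -0.57 ± 0.10 (0.00160). Of 8 globin genes 4 fell (4 over the list alone, median -1.26, camera adjusted p = 0.000125, adjusted p = 0.329 with an estimated correlation). None of these 4, HBQ1 (-1.01 ± 0.21, 0.00532), HBD, HBZ and HBA1, which has a near-identical copy, was called without DMSO replicate 2 (0.0566, 0.0694, 0.0715 and 0.1114) or GSK343 replicate 2 (0.0563, 0.1201, 0.0911 and 0.1324). Endoplasmic reticulum chaperones were lower too (8 down and 1 up of 18, both ways of adjusting, median -0.32, camera adjusted p = 9.43e-05, adjusted p = 0.342 with an estimated correlation).

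CDKN1A, the p21 inhibitor of cell cycle kinases, rose from 17.6 ± 0.181 to 91.8 ± 1.09 CPM with GSK343 (log2 2.38 ± 0.14, edgeR adjusted p = 8.81e-08), though the 17 cell cycle arrest genes did not pass as a list (3 up and 0 down by either adjustment, median -0.05 and mean 0.27, camera up at adjusted p = 0.330). Apoptosis regulators rose (9 up and 1 down of 27, 9 and 2 over the list alone, median 0.24, camera adjusted p = 0.00677, adjusted p = 0.238 with an estimated correlation), with members that act both ways. MCL1 (0.86 ± 0.12, 0.000287) and BCL2 (1.58 ± 0.28, 0.00170) are survival proteins, while BBC3 (0.53 ± 0.10, 0.00318, not called without GSK343 replicate 2, 0.0540) and BCL2L11 (0.61 ± 0.12, 0.00422, not called without GSK343 replicate 1, 0.0518) promote cell death. EZH1, the paralog of EZH2, fell from 73.6 ± 17.5 to 36.7 ± 7.58 CPM (0.000669). The other measured lists gave smaller or opposing values: PRC2 0 up and 1 down of 12 (camera adjusted p = 0.0664), REST corepressors 0 and 1 of 13 (0.0987), ATF4 targets 5 and 1 of 34 (0.0775), oxidative stress targets 2 and 4 of 21 (0.0553), hypoxia genes 2 and 2 of 30 (0.887), interferon genes 3 and 0 of 27 (0.194), ribosome biogenesis genes 0 and 2 of 24 (0.154). Cholesterol genes gave 2 and 0 of 29 (0.594), and metallothioneins with zinc exporters 0 and 0 of 11 by edgeR (0.695). Heat shock genes leaned lower (1 up and 0 down of 17 by either adjustment, median -0.35, camera adjusted p = 0.0229, adjusted p = 0.578 with an estimated correlation), a call that was lost without GSK343 replicate 1 (0.158) and turned upward without DMSO replicate 2 (0.239). That DMSO library stood apart in heat shock genes, with HSPA1A at 312 CPM against 46.9 in the other. Markers of other cell types did not pass as lists (myeloid 3 up and 1 down of 15, camera adjusted p = 0.194; lymphoid 2 and 0 of 9, 0.0553; fibroblast and epithelial 2 and 1 of 9, 0.186). The number of GSK343 calls depended on single libraries: 4287 without DMSO replicate 1, 1151 without DMSO replicate 2, 1449 without GSK343 replicate 1 and 739 without GSK343 replicate 2, and 1118 when the model held the 2 groups alone or 1542 when it held the 72 h groups.

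**Figure D2:**
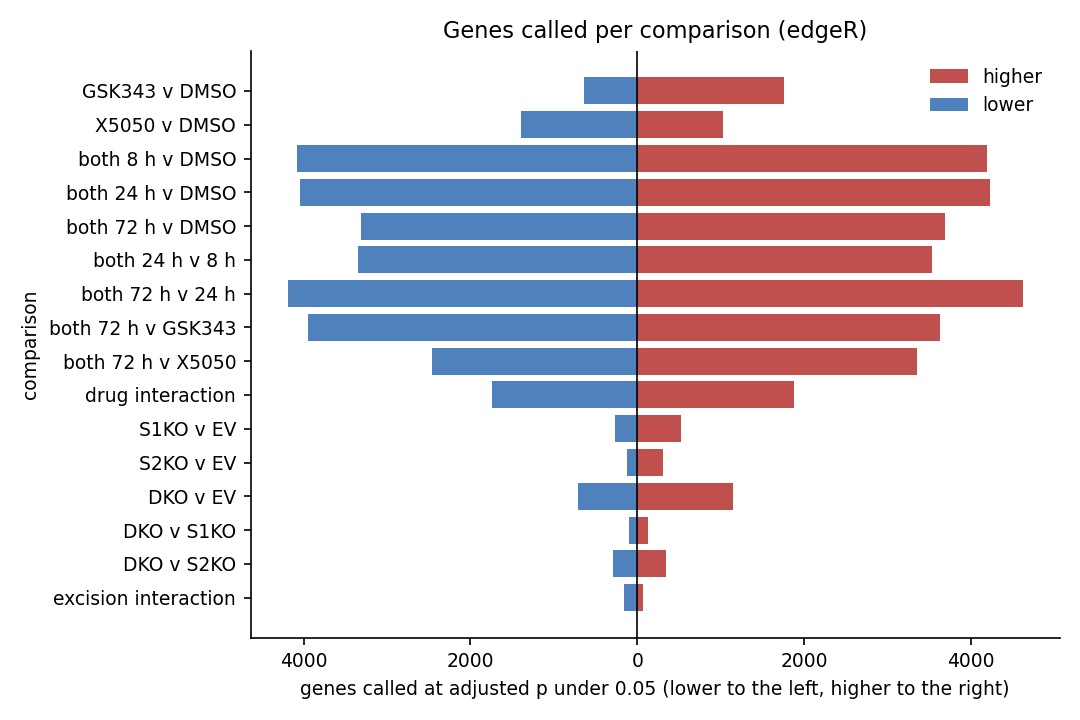
Genes called by edgeR at adjusted p below 0.05 in each comparison, with genes lower in the named group to the left and higher to the right. Each group has n = 2 libraries.

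What did the REST inhibitor do? Among genes of at least 2 CPM the largest rise was that of CXCL8, the neutrophil chemokine interleukin 8, from 0.735 ± 0.304 to 46.6 ± 6.60 CPM (log2 5.98 ± 0.30, edgeR adjusted p = 2.96e-07). The interferon-induced helicase gene DDX60 (5.43 ± 0.66), AHNAK2 (4.37 ± 0.33) and TNFRSF9, a T cell costimulator (3.62 ± 0.26), rose with it, and so did VGF (3.51 ± 0.35) and PTPRN (3.46 ± 0.34), which serve neuroendocrine secretory granules; their adjusted p was at or below 0.000318. Large falls were SIPA1L2 (-3.80 ± 0.45), CPXM1 (-3.51 ± 0.63), FAM178B, from 145 ± 55.5 to 15.2 ± 1.06 CPM, the antithrombin gene SERPINC1 (-3.07 ± 0.46) and CCDC144A (-2.66 ± 0.39), with adjusted p at or below 0.00461. Of 2415 genes called, 1026 rose and 1389 fell, 311 and 453 of them beyond 1 log2 unit. Rises outnumbered falls with RLE size factors (1182 and 1121), DESeq2 (1326 and 1231), no filter (1398 and 1348) and without X5050 replicate 1 (433 and 382) or 2 (1397 and 1053).

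The REST target genes of neurons rose with X5050, 10 up and 1 down of 29 (11 and 2 over the list alone, median log2 0.45, camera adjusted p = 0.000140, but adjusted p = 0.0749 with an estimated correlation). Besides VGF, from 1.47 ± 0.953 to 16.7 ± 5.80 CPM, they included the synaptic vesicle gene SYP (2.31 ± 0.28, edgeR adjusted p = 9.47e-05) and CALB1 (1.22 ± 0.16, 0.000184), while the granule protein gene SCG3 fell (-1.13 ± 0.14, 0.000153). Metallothioneins and zinc exporters, which buffer and export metal ions, rose (5 up and 0 down of 11, 7 and 0 over the list alone, median 3.42, or 2.79 with genes of 0 to 3 counts at their bound, camera adjusted p = 0.000140, adjusted p = 0.207 with an estimated correlation). MT2A went from 0.711 ± 0.0703 to 11.7 ± 0.273 CPM (9.74e-05). MT1G had a ratio of 96.1 (counting interval 16.9 to 3829), MT1X of 45.5 (12.3 to 380.2), and MT1H, absent from DMSO, was at least 14.7-fold higher. Reads of these near-identical genes may map to several copies and go uncounted, or be assigned to the wrong copy. Megakaryocytic genes rose (5 up and 0 down of 14, 6 and 0 over the list alone, median 0.61, camera adjusted p = 0.000267, adjusted p = 0.0749 with an estimated correlation). GP6 was at 2.41 ± 0.23 (9.76e-06) and ITGB3 at 2.697 ± 0.33 (0.000114).

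Endoplasmic reticulum chaperone and DNA replication genes fell with X5050. Of 18 endoplasmic reticulum chaperone and quality control genes 10 fell and 0 rose (15 and 0 over the list alone, median log2 -0.65, camera adjusted p = 8.55e-09, adjusted p = 0.2998 with an estimated correlation), such as DNAJB11 (-0.88 ± 0.13, edgeR adjusted p = 0.000676) and SEC61B (-0.72 ± 0.11, 0.000737). Of 29 DNA replication genes 12 fell and 0 rose (18 and 1 over the list alone, median -0.35, camera adjusted p = 2.22e-07, adjusted p = 0.455 with an estimated correlation). CDT1 fell from 517 ± 37.6 to 219 ± 15.4 CPM (9.55e-06) and TK1 by 0.90 ± 0.12 log2 (0.000184), whereas the 30 mitosis genes did not pass (1 up and 3 down, 1 and 4 over the list alone, median -0.06, camera adjusted p = 0.688). ATF4 targets of the amino acid response fell (13 down and 0 up of 34, 15 and 0 over the list alone, median -0.31, camera adjusted p = 6.02e-05, adjusted p = 0.569 with an estimated correlation). ATF5 was at -1.63 ± 0.22 (0.000714) and the mitochondrial serine enzyme gene SHMT2 at -0.84 ± 0.11 (0.000180). That list was not called without DMSO replicate 1 (0.0637) or X5050 replicate 1 (0.0837). Heat shock genes did not pass (2 up and 0 down of 17 by either adjustment, median 0.18 and mean -0.04, camera up at adjusted p = 0.0692). The 2 were HSPA8 (0.743 ± 0.207, 0.0365) and HSPH1 (0.845 ± 0.246, 0.0475), neither called without X5050 replicate 1 (0.314 and 0.2876) or DMSO replicate 1 (0.2308 and 0.0965).

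MCL1 rose from 221 ± 23.4 to 643 ± 40.4 CPM with X5050 (edgeR adjusted p = 3.02e-06), in an apoptosis list with 4 up and 0 down of 27 by either adjustment (median log2 0.15, camera adjusted p = 0.00516, adjusted p = 0.252 with an estimated correlation). Interferon genes moved both ways (6 up and 2 down of 27, 7 and 2 over the list alone, median 0.14, mean 0.77, camera adjusted p = 0.135). IFIT3 rose by 2.12 ± 0.29 (0.000331) and IFITM3 by 1.14 ± 0.14 (0.000114), OASL, absent from DMSO, was at least 26.6-fold higher, and OAS3 fell by 1.33 ± 0.15 (7.75e-05). Cell surface genes that rose were CD44 (2.66 ± 0.36, 0.000444), L1CAM (2.05 ± 0.30, 0.000667) and ICAM3 (1.23 ± 0.18, 0.000469), and the epithelial splicing factor gene ESRP1, which GSK343 raised, fell (-3.28 ± 0.60, 0.00247). FGF signalling genes had 3 up and 0 down of 18 (5 and 0 over the list alone, median 0.21, camera adjusted p = 0.0148, adjusted p = 0.207 with an estimated correlation, and 0.0975 without X5050 replicate 2). SPRY4 rose by 1.39 ± 0.14 (2.12e-05). The 9 silencer locus genes had 0 up and 0 down by edgeR, with no call over the list alone either (median -0.35, camera adjusted p = 0.618). The call count fell to 815 without X5050 replicate 1, to 617 with the model held to the 2 groups and to 1313 with the 72 h groups.

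What happened when both repressors were blocked for 72 h? The metal response came on from near silence. MT1H and MT1E, absent from DMSO, reached 47.5 ± 13.6 and 27.7 ± 3.57 CPM, at least 789-fold and 451-fold higher. MT1G had a ratio of 3480 (counting interval 624 to 1.38e+05), MT1X of 817 (226 to 6751) and MT1F of 707 (196 to 5848), and MT2A rose from 0.711 ± 0.0703 to 336 ± 129 CPM (log2 8.88 ± 0.37, edgeR adjusted p = 1.43e-08). ARC, the synaptic immediate early gene, rose from 0.243 ± 0.0520 to 144 ± 5.97 CPM (2.53e-11), and CCR7, the lymph node homing receptor, from 0 counts to at least 151-fold higher. Among the falls were genes that also fell with X5050, such as SIPA1L2 (-3.55 ± 0.45), CCDC144A (-3.47 ± 0.42) and FAM178B (-3.03 ± 0.25), as well as TAFA2 (-3.34 ± 0.46), the GABA receptor gene GABRG1 (-3.23 ± 0.44) and the transferrin gene TF (-3.05 ± 0.27), all with adjusted p at or below 0.000580. Of 7005 genes called, 3688 rose and 3317 fell, 2075 and 932 of them beyond 1 log2 unit. As a list, metallothioneins and zinc exporters had 10 up and 1 down of 11 by either adjustment (median 8.88, or 8.82 with low-count genes at their bound, camera adjusted p = 8.03e-07, adjusted p = 0.0784 with an estimated correlation).

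The REST target genes of neurons rose, 20 up and 1 down of 29 (21 and 1 over the list alone, median log2 1.35, camera adjusted p = 3.82e-06, and adjusted p = 0.0390 with an estimated correlation). TUBB3, neuronal tubulin, rose by 5.71 ± 0.37 (edgeR adjusted p = 1.61e-08), the axon adhesion gene L1CAM from 1.92 ± 0.905 to 57.5 ± 4.63 CPM (2.33e-08), VGF from 1.47 to 50.3 ± 1.34 CPM (9.95e-07) and SYP by 2.34 ± 0.28 (9.22e-06). Developmental transcription factors did not pass (1 up and 3 down of 21 by either adjustment, median -0.14, camera adjusted p = 0.444). The 9 genes of the silencer locus had 5 up and 1 down by either adjustment (median 0.37, camera adjusted p = 0.0148, adjusted p = 0.388 with an estimated correlation). SH3PXD2B was at 2.63 ± 0.24 (7.25e-07) and UBTD2 at 1.59 ± 0.29 (0.000526) beside FGF18. FGF signalling genes had 9 up and 3 down of 18 (median 0.20, mean 1.00, camera adjusted p = 0.228), the inhibitors DUSP4 (4.03 ± 0.31, 1.05e-07), DUSP5 (3.52 ± 0.21, 8.72e-09) and SPRY4 (1.61 ± 0.14, 4.36e-07) rising while FGF2 fell (-1.31 ± 0.16, 9.08e-06).

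Cell cycle exit genes rose and dividing-cell genes fell with both drugs. Of 17 cell cycle arrest genes 11 rose and 0 fell by either adjustment (median log2 1.07, camera adjusted p = 1.25e-05, adjusted p = 0.0784 with an estimated correlation). GADD45B, a stress-induced arrest gene, went from 2.20 ± 0.624 to 169.6 ± 0.182 CPM (edgeR adjusted p = 3.86e-12), CDKN1A from 17.6 ± 0.181 to 155 ± 33.3 (2.99e-10), and KLF6 and KLF4 rose by 3.19 ± 0.17 and 3.61 ± 0.35. DNA replication genes fell, 27 down and 0 up of 29 by either adjustment (median -0.90, camera adjusted p = 5.89e-17, adjusted p = 0.204 with an estimated correlation). CDC6 went from 162 ± 20.2 to 64.0 ± 3.89 CPM (5.49e-07), and RRM1 (-1.07 ± 0.11) fell too. Of 30 mitosis genes 22 fell and 0 rose (24 and 0 over the list alone, median -0.59, camera adjusted p = 1.89e-09, adjusted p = 0.388 with an estimated correlation). TOP2A fell by 1.17 ± 0.13 and NDC80 by 0.98 ± 0.11. Apoptosis genes rose (14 up and 2 down of 27, 15 and 2 over the list alone, median 0.72, camera adjusted p = 0.000218, adjusted p = 0.128 with an estimated correlation). The members that moved act both ways: BBC3 (1.17 ± 0.10) and BMF (2.43 ± 0.23) promote cell death, MCL1 (2.10 ± 0.13) and XIAP (1.20 ± 0.13) block it.

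Stress programs moved in opposite directions with both drugs. Heat shock genes rose (9 up and 1 down of 17, 11 and 1 over the list alone, median log2 1.32, camera adjusted p = 1.25e-05, adjusted p = 0.391 with an estimated correlation). HSPH1 went from 53.1 ± 22.4 to 264 ± 24.2 CPM (edgeR adjusted p = 3.98e-05) and the cochaperone gene BAG3 rose by 1.32 ± 0.16 (9.93e-06). Oxidative stress targets rose (12 up and 1 down of 21, 12 and 2 over the list alone, median 0.45, camera adjusted p = 0.00296, adjusted p = 0.391 with an estimated correlation). OSGIN1 was at 2.81 ± 0.16 (3.48e-09) and the ferritin gene FTL at 1.81 ± 0.14 (9.18e-08). ATF4 targets fell (19 down and 8 up of 34, 20 and 8 over the list alone, median -1.11, camera adjusted p = 2.97e-06, adjusted p = 0.429 with an estimated correlation). Asparagine synthetase, ASNS, went from 1431 ± 60.1 to 342 ± 8.41 CPM (1.31e-07), and PSAT1 of serine synthesis (-2.02 ± 0.16, 1.98e-07) and WARS1, a tRNA synthetase (-2.04 ± 0.15, 6.15e-08), fell. Endoplasmic reticulum chaperones fell (14 down and 1 up of 18, 15 and 2 over the list alone, median -0.88, camera adjusted p = 1.54e-05, adjusted p = 0.391 with an estimated correlation). HYOU1 fell by 1.27 ± 0.14 (2.82e-06). Cholesterol genes fell (11 down and 0 up of 29, 11 and 1 over the list alone, median -0.43, camera adjusted p = 0.000274, adjusted p = 0.463 with an estimated correlation). ACAT2 fell by 1.00 ± 0.11 (5.71e-06), and the call of the list was lost without DMSO replicate 2 (0.428). Hypoxia genes rose (12 up and 2 down of 30 by either adjustment, median 0.25, camera adjusted p = 0.0120, adjusted p = 0.458 with an estimated correlation). NDRG1 rose by 2.62 ± 0.16 (9.01e-09), and the call of the list was lost without DMSO replicate 1 (0.115).

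Immune genes rose and blood lineage genes split with both drugs. Interferon genes rose (12 up and 2 down of 27 by either adjustment, median log2 0.79, camera adjusted p = 0.0124, adjusted p = 0.388 with an estimated correlation), led by the factors IRF1 (1.94 ± 0.18, edgeR adjusted p = 6.72e-07) and IRF7 (1.37 ± 0.18, 2.34e-05). Antigen presentation genes rose (7 up and 1 down of 15, 8 and 1 over the list alone, median 0.61, camera adjusted p = 0.0205, adjusted p = 0.429 with an estimated correlation). HLA-E was at 1.33 ± 0.16 and B2M at 0.87 ± 0.12. Adhesion genes rose (11 up and 1 down of 24 by either adjustment, median 0.51, camera adjusted p = 0.00296, adjusted p = 0.388 with an estimated correlation). CD44 went from 1.02 to 43.6 ± 14.7 CPM (7.06e-08) and ICAM1 rose by 2.01 ± 0.18 (1.23e-06). Globins rose (7 up and 1 down of 8 by either adjustment, median 1.52, camera adjusted p = 0.0120, adjusted p = 0.463 with an estimated correlation). Embryonic HBE1 went from 384 ± 21.8 to 1179 ± 213 CPM (0.000411) and HBZ rose by 2.34 ± 0.41 (0.000330), while HBQ1 fell (-1.49 ± 0.22, 6.62e-05). Other erythroid genes fell (14 down and 2 up of 32, 15 and 3 over the list alone, median -0.35, camera adjusted p = 0.00208, adjusted p = 0.498 with an estimated correlation), including the glycophorin gene GYPE (-1.66 ± 0.15) and the factor NFE2 (-0.78 ± 0.15).

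Lists that did not pass camera with both drugs still held large single changes. Myeloid markers had 5 up and 4 down of 15 by either adjustment (median log2 0.05, mean 0.93, camera adjusted p = 0.819), with the integrin gene ITGAX at 5.84 ± 0.36 (edgeR adjusted p = 9.23e-09). Megakaryocytic genes had 5 up and 2 down of 14 (median 0.36, mean 1.12, camera adjusted p = 0.228), with ITGB3 at 4.12 ± 0.32 (1.07e-07). Fibroblast and epithelial markers had 3 up and 2 down of 9 (median 0.73, camera adjusted p = 0.778), with the keratin gene KRT19 from 71.5 ± 10.3 to 253 ± 24.3 CPM (1.00e-06). Lymphoid markers had 3 up and 2 down of 9, or 4 and 2 over the list alone (0.819), HOX genes 1 and 3 of 17 (0.444) with HOXB9 at -0.88 ± 0.12, and histone genes 4 and 3 of 16 with a median of -0.09 against a mean of 0.16 (0.819). PRC2 genes had 3 and 4 of 12 (0.891), REST corepressors 2 and 2 of 13 (0.713) and ribosome biogenesis genes 3 and 6 of 24 (0.965).

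Where does the response start? At 8 h of both drugs 8268 genes differed from the 72 h DMSO libraries (4194 up, 4074 down) and at 24 h 8277 (4228 up, 4049 down). The 8 h and 24 h libraries stand apart from all 72 h libraries in base composition. In gene quintiles by GC content, the median deviation of the highest less the lowest was -0.784 and -0.548 log2 units at 8 h and -0.663 and -0.627 at 24 h, against 0.526 and 0.582 with both drugs at 72 h and 0.351 and 0.106 in DMSO. With this trend removed, 7418 genes were called at 8 h, 5806 of them in the same direction as before, and 7320 at 24 h, with 5845 so kept. No DMSO library was taken at 8 h or 24 h, so time and library set cannot be separated.

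**Figure D3:**
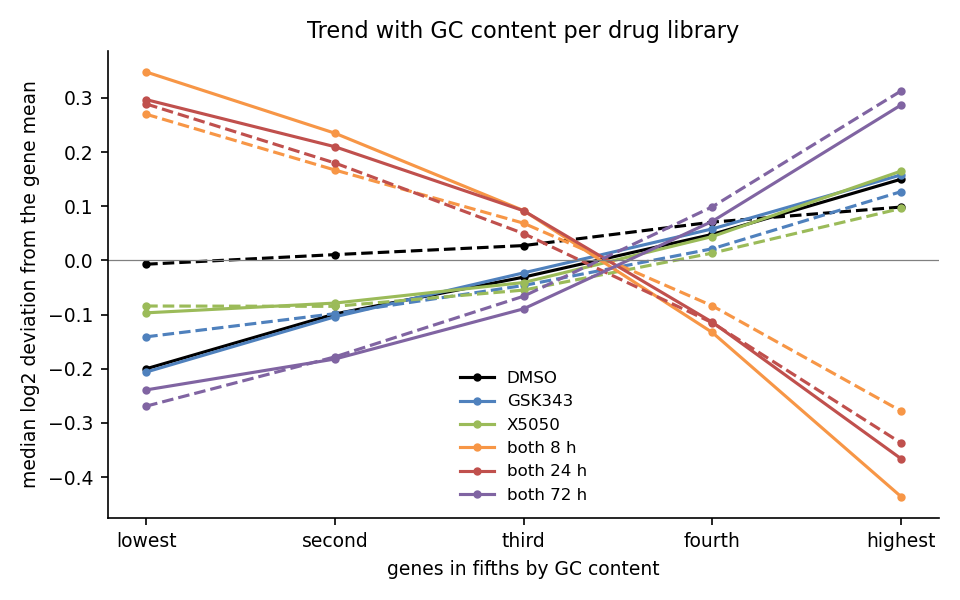
Median log2 deviation from the gene mean in each quintile of genes by GC content, for each library of the drug arm. Solid lines are replicate 1 and dashed lines replicate 2 (n = 2 per group).

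At 8 h CXCL8 was at 180.4 ± 9.79 CPM against 0.735 ± 0.304 in DMSO (log2 7.94 ± 0.30, edgeR adjusted p = 6.72e-09), and EGR3 (5.70 ± 0.52, 8.11e-07) and the small GTPase gene RRAD (5.07 ± 0.43, 9.64e-07) were high, while ACVRL1 (-4.74 ± 0.69, 0.000418), LGALS12 (-3.81 ± 0.41, 3.10e-06) and CPXM1 (-3.73 ± 0.63, 0.000518) were low. Cholesterol genes were lower than in DMSO (24 down and 1 up of 29 by either adjustment, median -1.09, camera adjusted p = 1.05e-08, adjusted p = 0.645 with an estimated correlation). MVK was at -2.03 ± 0.19, MVD at -1.82 ± 0.15 and LSS at -1.50 ± 0.12. HOX genes were lower (8 down and 0 up of 17 by either adjustment, median -0.80, camera adjusted p = 0.00838, adjusted p = 0.645 with an estimated correlation). HOXB6 fell by 2.67 ± 0.21. Ribosome biogenesis genes were higher (15 up and 1 down of 24, 16 and 1 over the list alone, median 0.51, camera adjusted p = 0.000254, adjusted p = 0.842 with an estimated correlation). UTP20 rose by 1.06 ± 0.15. The REST target genes had 15 up and 4 down of 29 by either adjustment (median 0.96, camera adjusted p = 0.00956, adjusted p = 0.410 with an estimated correlation). GDAP1 was at 3.83 ± 0.37 and VGF at 3.38 ± 0.35, and the call of the list was lost without DMSO replicate 2 (0.0711).

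At 24 h CXCL8 reached 1145 ± 14.5 CPM (log2 10.60 ± 0.32, edgeR adjusted p = 9.17e-11), and the interleukin 7 receptor gene IL7R, absent from DMSO, was at least 203-fold higher. WSCD2 (-4.86 ± 0.61, 0.000159), FAM178B (-4.37 ± 0.27, 2.79e-07) and KDF1 (-3.85 ± 0.37, 8.96e-07) were lower. Oxidative stress targets were higher (15 up and 1 down of 21 by either adjustment, median 1.09, camera adjusted p = 2.04e-06, adjusted p = 0.240 with an estimated correlation). OSGIN1 rose by 3.36 ± 0.16, TXNRD1 by 2.08 ± 0.12 and NQO1 by 2.07 ± 0.15. Heat shock genes were higher (12 up and 0 down of 17 by either adjustment, median 0.78, camera adjusted p = 2.04e-06, adjusted p = 0.434 with an estimated correlation). HSPA8 rose by 2.32 ± 0.22. Erythroid genes were lower (21 down and 1 up of 32 by either adjustment, median -0.89, camera adjusted p = 2.04e-06, adjusted p = 0.434 with an estimated correlation). NFE2 fell by 2.09 ± 0.16. The REST target gene VGF stood at 281.1 ± 20.98 CPM, SYP at 36.1 ± 1.12 and CALB1 at 52.0 ± 1.17, each above its level at 72 h of both drugs.

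Between 8 h and 24 h 6880 genes differed (3534 up, 3346 down). NRP1 rose by log2 6.24 ± 0.50 (edgeR adjusted p = 1.01e-06), IL7R by 6.21 ± 0.45 (1.63e-07), PAEP by 5.91 ± 0.48 (3.01e-06) and CES1 by 7.32 ± 1.09 (0.000983), while CAPN5 (-3.599 ± 0.31, 4.77e-07), FNDC5 (-3.47 ± 0.40, 7.57e-06), ZNF425 (-3.31 ± 0.30, 8.48e-07) and NGFR (-3.29 ± 0.46, 0.000268) fell. Erythroid genes fell (24 down and 0 up of 32 by either adjustment, median -1.05, camera adjusted p = 3.15e-11, adjusted p = 0.439 with an estimated correlation) and oxidative stress targets rose (16 up and 0 down of 21 by either adjustment, median 0.85, camera adjusted p = 8.34e-10, adjusted p = 0.439 with an estimated correlation). From 24 h to 72 h 8818 genes differed (4625 up, 4193 down), and mitosis genes fell (24 down and 0 up of 30 by either adjustment, median -0.95, camera adjusted p = 3.89e-12, adjusted p = 0.550 with an estimated correlation). HMMR fell by 1.79 ± 0.10 and TOP2A by 1.46 ± 0.13. ACP5 (6.24 ± 0.61, 5.82e-05) and SLC2A6 (5.50 ± 0.40, 9.02e-08) rose, and F2RL2 (-4.48 ± 0.38, 3.97e-07), FLT1 (-4.02 ± 0.27, 4.70e-08) and IL7R (-3.29 ± 0.36, 5.08e-06) fell. With the GC trend removed 6628 genes differed between 24 h and 72 h, 4986 in the same direction as before, 74 turned, and the median of all genes moved from 0.07 to 0.10.

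Which changes needed both drugs? Against GSK343 alone 7578 genes differed at 72 h (3628 up, 3950 down) and against X5050 alone 5816 (3360 up, 2456 down). The excess of rises over X5050 turned with DESeq2 (2605 up, 2784 down), no filter (3018 and 3032) and without X5050 replicate 1 (2106 and 2159) or 2 (2202 and 2705). Several genes that GSK343 had raised were far lower with X5050 added: ESRP1 (log2 -5.63 ± 0.55, edgeR adjusted p = 1.57e-06), CYP4F2 (-5.14 ± 0.52, 2.16e-06), ADGRG6 (-5.45 ± 0.54, 1.56e-06) and KBTBD11 (-4.94 ± 0.50, 2.01e-06). Developmental transcription factors were lower than with GSK343 alone (11 down and 1 up of 21 by either adjustment, median -1.01, camera adjusted p = 0.00294, adjusted p = 0.109 with an estimated correlation), and heat shock genes higher (14 up and 1 down of 17, 16 and 1 over the list alone, median 1.31, camera adjusted p = 4.13e-07, adjusted p = 0.414 with an estimated correlation). Against X5050 alone MT1E was higher (6.01 ± 0.41, 2.16e-07) and the factor SOX5 lower (-2.18 ± 0.22, 3.68e-06). Mitosis genes were lower than with X5050 alone (22 down and 0 up of 30, 24 and 0 over the list alone, median -0.48, camera adjusted p = 4.55e-11, adjusted p = 0.360 with an estimated correlation), and the silencer locus was higher (5 up and 0 down of 9 by either adjustment, median 0.47, camera adjusted p = 0.00898, adjusted p = 0.360 with an estimated correlation).

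The interaction test, which asks for more or less than the single drugs add up to on the log scale, called 3613 genes (1875 above, 1738 below). More genes stood below than above with RLE size factors (1930 against 1658), DESeq2 (2065 against 1676), unstranded counts (1962 against 1647) and no filter (2040 against 1846), and without DMSO replicate 2 (1717 against 1608), GSK343 replicate 1 (1356 against 1117) or X5050 replicate 1 (1560 against 1457) or 2 (1692 against 1301). Above the sum stood arrest, heat shock and metal genes. RASD1, a RAS-related gene, was at 9.58 CPM with both drugs against 0.142 in DMSO, 0.0486 with GSK343 and 0.0678 with X5050 (edgeR adjusted p = 0.000323). Its 1 and 2 counts with GSK343 allow no fold. DEPP1 was at 25.7 CPM against 2.96, 1.53 and 2.29 (log2 4.44 ± 0.44, 1.68e-05). Cell cycle arrest genes had 10 above and 0 below of 17 (13 and 1 over the list alone, median 0.93, camera adjusted p = 2.13e-05, adjusted p = 0.236 with an estimated correlation). GADD45B was at 3.61 ± 0.26 and CDKN1C at 2.44 ± 0.25. Heat shock genes had 9 above and 0 below of 17 (10 and 0 over the list alone, median 0.88, camera adjusted p = 2.13e-05, adjusted p = 0.582 with an estimated correlation). BAG3 was at 1.73 ± 0.22. Metallothioneins and zinc exporters had 3 above and 0 below of 11 by either adjustment (camera adjusted p = 0.000603, adjusted p = 0.236 with an estimated correlation). SLC30A1 was at 4.02 ± 0.49. Below it stood INPP1 (-4.46 ± 0.44), PALD1 (-4.05 ± 0.47) and TRIM67 (-3.99 ± 0.63), which GSK343 alone had raised. ATF4 targets had 14 below and 2 above of 34 (17 and 4 over the list alone, median -0.86, camera adjusted p = 2.13e-05, adjusted p = 0.705 with an estimated correlation). PSAT1 was at -2.31 ± 0.22. The REST target genes split, 3 above and 4 below of 29 by either adjustment (median -0.14, mean 0.05, camera adjusted p = 0.563), with TUBB3 at 3.79 ± 0.64 and CALB1 at -1.83 ± 0.22. The count of genes was 2296 without replicate 1 of both drugs at 72 h and 2391 without GSK343 replicate 2, and 2314 with the 4 groups alone in the model.

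**Figure D4:**
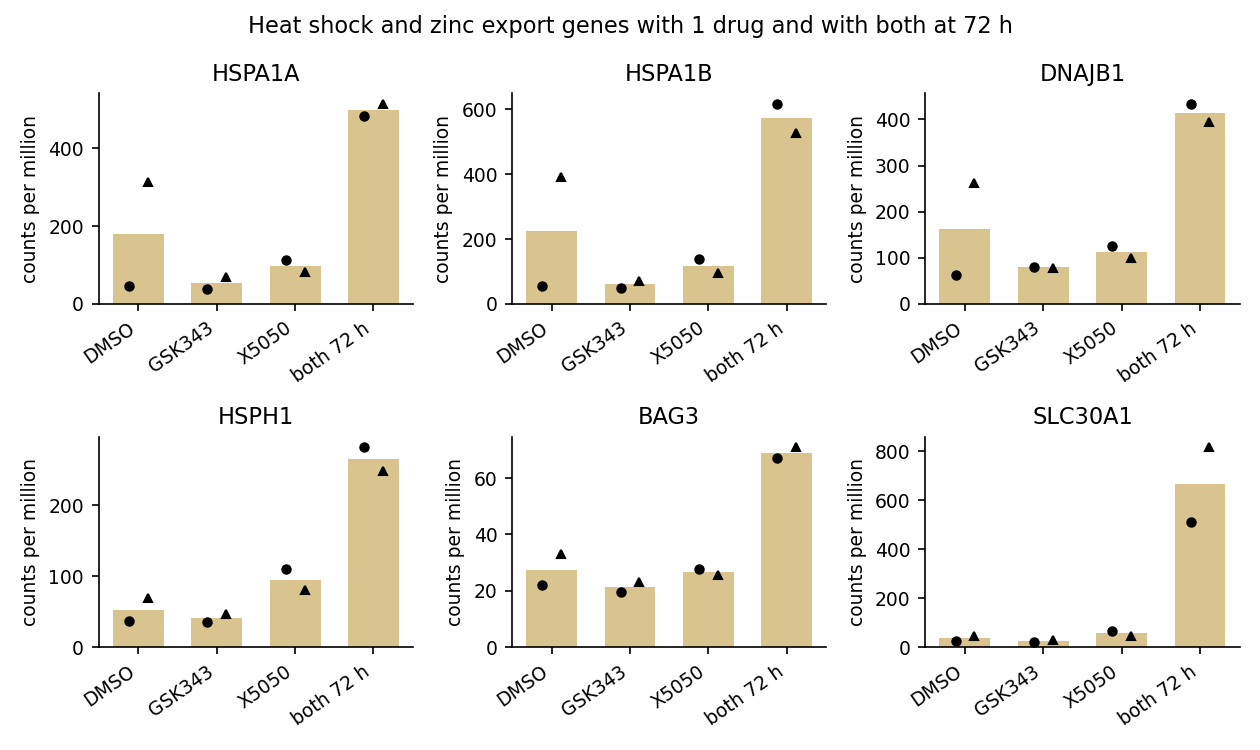
Heat shock genes and the zinc exporter gene SLC30A1 in CPM at 72 h in DMSO, GSK343, X5050 and both drugs. Bars are means of n = 2 libraries, circles replicate 1 and triangles replicate 2.

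Which genes differ between the edited cells and EV? The labels do not say whether the 2 libraries of a group come from separately edited populations. Below, an excision effect and a difference between cell populations therefore cannot be told apart. Without silencer 1, EFEMP1, an extracellular matrix glycoprotein gene, rose from 0.0611 ± 0.0149 to 43.9 ± 5.29 CPM (log2 9.45 ± 0.29, edgeR adjusted p = 9.00e-05). The histone gene H2BC12, with 12139 counts in EV, had 0 in S1KO and was at least 4762-fold lower, and the zinc finger gene ZNF521 fell by 9.41 ± 0.80 (0.00215). SCG3 rose from 2.81 ± 0.452 to 574 ± 3.36 CPM (9.00e-05), and SCN2A by 7.72 ± 0.92 (0.00771), among REST target genes with 3 up and 0 down of 29 (4 and 0 over the list alone, median 0.27, camera adjusted p = 0.0151, adjusted p = 0.425 with an estimated correlation, and 0.139 without EV replicate 2). Embryonic globin HBE1 rose from 133 ± 51.2 to 3791 ± 1155 CPM (0.00304), with 2 up and 0 down of 10 globin genes by either adjustment (median 2.03, camera adjusted p = 0.000880, adjusted p = 0.735 with an estimated correlation). Megakaryocytic genes rose (5 up and 0 down of 17, 7 and 1 over the list alone, median 1.24, camera adjusted p = 7.42e-05, adjusted p = 0.213 with an estimated correlation). RAB27B rose by 5.29 ± 0.38 (0.00119) and the platelet glycoprotein gene GP1BB by 3.53 ± 0.25 (0.00108). Of 781 genes called 520 rose and 261 fell; the count was 446 without EV replicate 1, 394 without EV replicate 2, 262 and 249 without S1KO replicate 1 and 2, and 300 with the model held to these 2 groups.

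Without silencer 2, 427 genes were called (309 up, 118 down). IKZF3, a lymphoid factor, rose by log2 7.76 ± 0.48 (edgeR adjusted p = 0.00131), TUBA3C had a ratio of 976 (counting interval 334 to 4736), and ADAMTS9, a matrix protease gene, fell by 5.64 ± 0.35 (0.00131). Erythroid genes rose (4 up and 0 down of 33, 10 and 0 over the list alone, median 0.49, camera adjusted p = 1.76e-10, adjusted p = 0.776 with an estimated correlation). Carbonic anhydrase gene CA2 was at 6.92 ± 0.53 (0.00257) and the band 3 gene SLC4A1 at 3.54 ± 0.47 (0.0177), the latter not called without EV replicate 1 (0.0951) or 2 (0.0643). HBE1 rose to 2095 ± 814 CPM (0.00811), with 2 up and 0 down of 10 globin genes by either adjustment (median 2.00, camera adjusted p = 0.000116, adjusted p = 0.776 with an estimated correlation, and 0.0691 without S2KO replicate 1). ITGB5 rose by 2.45 ± 0.18 (0.00252) and GP1BB by 2.87 ± 0.24 (0.00389). Mitochondrial genome mRNAs were lower as a list (0 up and 0 down of 13 by edgeR, 0 and 6 over the list alone, median -0.40, camera adjusted p = 0.000141, adjusted p = 0.776 with an estimated correlation, and 0.415 without EV replicate 1). With only S2KO and EV in the model edgeR called 0 genes, with 1347 at an unadjusted p under 0.05, while DESeq2 with all groups called 1082. The count was 157 without EV replicate 1, 169 without EV replicate 2 and 226 without S2KO replicate 2.

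With both silencers excised, 1866 genes were called (1152 up, 714 down). EHD3, a membrane trafficking gene absent from EV, reached 10.0 ± 0.0958 CPM, at least 544-fold higher. EFEMP1 rose from 0.0611 ± 0.0149 to 38.8 ± 1.08 CPM (log2 9.27 ± 0.29, edgeR adjusted p = 0.000159), the drug efflux pump gene ABCG2 had a ratio of 585 (counting interval 199.6 to 2839) and the gap junction gene GJA1 of 466 (129 to 3855). The collagen gene COL1A2 rose from 0.388 ± 0.0591 to 114 ± 14.4 CPM (0.000162). H2BC12 (at least 2992-fold) and the receptor gene GPR174 (at least 237-fold) were lost, TGFBR2, a TGF-beta receptor, fell from 16.04 ± 1.32 to 0.0494 ± 0.0215 CPM (0.000692), and ADAMTS9 from 12.4 ± 0.141 to 0.126 ± 0.0404 (0.000314). The phosphatase gene PTPN7 (-7.03 ± 0.75, 0.00310) and PRR16 (-7.22 ± 0.87, 0.00467) also fell.

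Red cell genes rose in DKO. Globins had 3 up and 0 down of 10 (8 and 0 over the list alone, median log2 3.36, camera adjusted p = 8.81e-05, adjusted p = 0.415 with an estimated correlation). HBE1 was at 6330 ± 514 CPM against 133 ± 51.2 in EV (edgeR adjusted p = 0.00123), and adult HBB had a ratio of 565 (counting interval 101 to 2.24e+04). The replicates of the other groups stood apart: globins were lower in replicate 2 than in replicate 1 by a median log2 of 1.57 in EV, 0.92 in S1KO and 1.52 in S2KO, and higher by 0.27 in DKO. ATF4 targets were higher in replicate 2 by 1.48, 1.90, 1.99 and 0.08 in these groups. Of 33 erythroid genes 8 rose and 0 fell (16 and 0 over the list alone, median 0.59, camera adjusted p = 1.37e-06, adjusted p = 0.312 with an estimated correlation). ALAS2, the first enzyme of heme synthesis in red cells, rose from 12.3 ± 0.953 to 155 ± 35.6 CPM (0.00229), CA2 by 6.33 ± 0.52 (0.00120) and HEMGN by 2.86 ± 0.40 (0.00779). Megakaryocytic genes had 5 up and 0 down of 17, or 5 and 2 over the list alone (median 0.48, camera adjusted p = 0.0462, adjusted p = 0.312 with an estimated correlation). CD9 was at 6.67 ± 0.41 (0.000392) and RAB27B at 4.57 ± 0.37 (0.00117). That list was not called without EV replicate 1 (0.0977) or EV replicate 2 (0.0581), nor with the length-scaled TPM counts (0.0812) or the GC trend removed (0.0631).

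Interferon genes rose in DKO (8 up and 0 down of 30, 10 and 0 over the list alone, median log2 0.76, camera adjusted p = 8.81e-05, adjusted p = 0.331 with an estimated correlation). IFIT3 rose by 4.60 ± 0.55 (edgeR adjusted p = 0.00450), and IFIT2 had a ratio of 235 (counting interval 41.7 to 9348). Immunoproteasome genes PSMB8 (4.37 ± 0.49, 0.00342) and PSMB9 (3.48 ± 0.43, 0.00477) rose in the antigen presentation list (5 up and 0 down of 12 by either adjustment, median 0.62, camera adjusted p = 0.0120, adjusted p = 0.312 with an estimated correlation, and 0.0737 without EV replicate 1). REST target genes had 3 up and 0 down of 29 by either adjustment (median 0.56, camera adjusted p = 0.0120, adjusted p = 0.312 with an estimated correlation). SCG3 went from 2.81 ± 0.452 to 188 ± 17.9 CPM (0.000159) and SCN2A rose by 7.87 ± 0.92 (0.00422). The homeobox and T-box genes MSX1 (2.86 ± 0.26, 0.00163) and TBX3 (6.18 ± 0.77, 0.00530) rose, ITGB5 went from 4.67 ± 0.102 to 66.0 ± 6.41 CPM (0.000239), and the death receptor gene FAS had a ratio of 247 (67.9 to 2046). Cholesterol genes were lower by camera (2 down and 0 up of 29 by either adjustment, median -0.43, camera adjusted p = 0.00128, adjusted p = 0.606 with an estimated correlation), and the DKO libraries differed from each other by as much (replicate 2 less replicate 1, median -0.4259). The metallothionein list had 1 up and 0 down of 6, or 3 and 0 over the list alone (median 1.19, camera adjusted p = 0.0120, adjusted p = 0.312 with an estimated correlation).

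At the excised locus DKO gave 1 gene up and 1 down of 13 by either adjustment (median log2 0.42, camera adjusted p = 0.355). These were SH3PXD2B (3.604 ± 0.58, edgeR adjusted p = 0.0128), not called without DKO replicate 1 (0.0829) or 2 (0.0607), and FBXW11, a ubiquitin ligase subunit gene (-1.51 ± 0.21, 0.00868), not called without DKO replicate 1 (0.0906) or 2 (0.0871). Mitosis genes had 0 up and 0 down of 30 by edgeR (camera adjusted p = 0.650), DNA replication genes 0 and 0 of 29 (0.213), ribosome biogenesis genes 0 and 0 of 25 (0.183) and mitochondrial genome mRNAs 1 and 3 of 13, or 3 and 4 over the list alone (median 0.11, camera down at 0.836). The DKO call count was 526 and 528 without DKO replicate 1 and 2 and 924 without EV replicate 2, and 3112 with DESeq2.

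Other lists passed camera in DKO but depended on single libraries or on the settings. With a replicate block the lymphoid, HOX, developmental, adhesion, REST corepressor and histone lists lost their call (camera adjusted p of 0.0513 to 0.0960). With the GC trend removed all of these but histones lost it (0.0670 to 0.0700). Endoplasmic reticulum chaperones (0 up and 0 down of 18 by edgeR, median log2 -0.64, camera adjusted p = 0.00128, 0.613 with an estimated correlation) and ATF4 targets (0 and 0 of 34, -1.17, 0.0111, 0.784) were lower, and heat shock genes (0 and 0 of 16, 0.73, 0.0458, 0.778) higher. None of the 3 passed without EV replicate 2 (0.2884, 0.7536 and 0.4491), nor heat shock genes without DKO replicate 2 (0.0514). Lymphoid markers were higher (3 up and 0 down of 9, 4 and 0 over the list alone, median 1.67, camera adjusted p = 0.0462, 0.358 with an estimated correlation), but not without any 1 of the DKO or EV libraries (0.0514 to 0.1535). HOX genes (2 up and 0 down of 22, camera adjusted p = 0.0462), developmental transcription factors (4 and 0 of 19, 0.0462) and adhesion genes (4 and 0 of 27, 0.0497) leaned higher, and REST corepressors (0 and 1 of 13, 0.0462) and histones (0 and 1 of 19, 0.0462) lower. Without EV replicate 1 these 5 were at 0.1629, 0.1772, 0.1629, 0.1787 and 0.9378, with histones turned upward, and without DKO replicate 1 developmental factors (0.0831), adhesion genes (0.0802) and histones (0.2355) did not pass either. Myeloid markers (2 and 0 of 15, 0.355) and fibroblast and epithelial markers (2 and 0 of 11, 0.0776) did not pass.

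Against S1KO, DKO differed at 233 genes (133 up, 100 down), and against S2KO at 631 (342 up, 289 down). With only the groups compared in the model this order turned, with more genes called against S1KO than against S2KO. ZPLD1, a zona pellucida domain gene, fell from 15.0 ± 3.20 CPM in S1KO to 0.101 ± 0.0511 in DKO (log2 -7.21 ± 0.46, edgeR adjusted p = 0.00306). Erythroid genes were higher in DKO than in S1KO (2 up and 0 down of 33, 7 and 0 over the list alone, median 0.51, camera adjusted p = 1.97e-06, adjusted p = 0.516 with an estimated correlation). Against S2KO, C5orf58 (8.93 ± 0.34, 0.000609), COL1A2 (7.95 ± 0.33, 0.000617) and CNTNAP3B (6.27 ± 0.62, 0.00515) rose, and interferon genes were higher (1 up and 0 down of 30, 4 and 0 over the list alone, median 0.76, camera adjusted p = 1.61e-05, adjusted p = 0.314 with an estimated correlation). The 233 genes became 24 (7 up, 17 down) and 17 (6 and 11) without DKO replicate 1 and 2, and 36 (6 and 30) and 17 (4 and 13) without S1KO replicate 1 and 2, so the side with more genes turned. The 631 became 102 and 101 without DKO replicate 1 and 2, and 302 and 269 without S2KO replicate 1 and 2. The test of whether DKO differs from the sum of the single excisions called 222 genes (68 above, 154 below), with TSPAN5 (6.03 ± 0.39, 0.00325) above and ZPLD1 (-7.74 ± 0.69, 0.00693) below.

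How far do the perturbations share genes? S1KO and DKO were called in the same direction at 659 genes (460 up, 199 down) where 28.1 and 8.76 would be expected, and 3 in opposite directions. S2KO and DKO shared 334 (260 up, 74 down; 16.7 and 3.96 expected), and 247 genes were called the same way in all 3 excisions (189 up, 58 down). X5050 and both drugs at 72 h shared 1527 (679 up, 848 down; 197 and 239.7 expected), GSK343 and both drugs 1038 (754 up, 284 down; 336 and 109.7 expected), and the single drugs 491 (321 up, 170 down; 93.6 and 45.9 expected). These pairs share control libraries, and part of the excess may come from them. Simulated unchanged groups gave at most 2 shared calls in 10 draws. Such groups yield hardly any calls, so this cannot show how many shared calls the controls add. The simulated libraries were independent, whereas equally numbered EV, S1KO and S2KO libraries were not (above). The covariance of the log2 fold changes was 1.38 for S1KO with DKO against 0.185 simulated, and 1.02 against 0.185 for S2KO with DKO. It was 0.563 against 0.0769 for X5050 with both drugs and 0.456 against 0.0759 for GSK343 with both drugs. The single drugs gave 0.160 against 0.0759. With a separate control library for each comparison, the covariance of log2 CPM differences was 0.226 and 0.2902 for S1KO with DKO, 0.0901 and 0.2005 for S2KO with DKO, 0.1425 and 0.1273 for X5050 with both drugs, 0.0790 and 0.0350 for GSK343 with both drugs, and 0.0136 and -0.0153 for the single drugs. With 1 library in common these ran from 0.056 for the single drugs to 0.4982 for S1KO with DKO, so the covariance of the single drugs may come from the controls. Between the arms, which share no library, DKO and GSK343 had 260 genes up in both against 84.6 expected (Fisher exact p = 1.08e-66) and 20 down in both against 22.5 (Fisher exact p = 0.662), with 90 called in opposite directions. DKO and both drugs had 261 up against 177 (Fisher exact p = 5.45e-12) and 152 down against 115.5 (Fisher exact p = 0.000224), with 213 in opposite directions. S1KO and both drugs did not pass (94 up against 83.2, Fisher exact p = 0.193, and 52 down against 44.4, Fisher exact p = 0.208), with 146 in the same and 142 in opposite directions. Fisher's test takes genes as independent, but called genes lay beside each other. GSK343 rises had 288 neighbouring pairs against a shuffled mean of 140.9, and DKO rises 92 against 43.11. The p values are therefore likely too small, and the expected numbers are not matched for expression level.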

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

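All tests here were chosen after the results were seen. Differences between the timepoints were singled out by their number of called genes, 6880 between 8 h and 24 h of both drugs and 8818 between 24 h and 72 h. A trend with GC content runs through the 8 h and 24 h libraries, and 4986 of the 8818 calls stayed in the same direction with it removed, which argues against the trend as the whole difference. The bound that at least 50% had to stay was set after 56.5% had been seen, so the calls that did not stay leave the trend open as part of it. Multimapping reads, a quantity outside the main measurement, averaged 26.41% with both drugs at 72 h, and the lowest 72 h library lies 5.7 percentage points above the highest 8 h or 24 h library. Library batch and treatment time cannot be told apart, because no other group was sampled at 8 h or 24 h.

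The interaction of the drugs was singled out by 3613 genes that departed from the sum of the single drugs, with heat shock and metal response genes above it. Of the 12 called members 10 had at least 100 counts in every library of the 4 groups, so counts near 0 do not account for these 10. The members were picked by the same test, which genes near 0 seldom pass, so this does not speak for the uncalled members. CRYAB and MT2A had smallest counts of 2 and 16. MT2A was the only metallothionein called, so counts near 0 stay open for the metallothioneins. DMSO replicate 2 was high in heat shock genes. Without it the median interaction of all 17 tested was log2 0.69 (95% interval over genes 0.0997 to 1.41), against 0.884 with it, with CRYAB, AHSA1 and MT2A no longer called. The interval takes genes as independent and omits library error, so that library stays open as a cause. Reads shared by the near-identical copies HSPA1A and HSPA1B do not account for the heat shock genes, whose median over the other 15 was 0.72 (0.412 to 1.82). Reads mapping to several metallothionein copies went uncounted, so the summed family lacks them. The sum of uniquely placed reads had an interaction of log2 3.71 (2.984 at the lowest over the 16 choices of 1 library per group). Uniquely placed reads assigned to the wrong copy within the family thus do not account for it. Reads lost as multimapping could not be tested this way, and single copies stay uncertain. Of the 3 tested metal genes without a near-identical copy, SLC30A1 was at 4.02, MTF1 at 0.65 and SLC30A10 at -0.53. Why the drugs together exceed their sum was not tested.

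Shared calls of S1KO and DKO were singled out because 84.4% of the S1KO calls recurred in DKO. With a separate EV library for each comparison the covariance of the log2 differences over all 21285 tested genes was 0.226 (95% interval over genes 0.2038 to 0.2468) and 0.2902. With the same EV library for both it was 0.3305 and 0.4982. Over all tested genes this argues against chance values of the shared EV libraries as the whole of the likeness. It does not show how many of the shared calls they add, and the interval does not cover the spread between EV libraries. If EV stood apart, K562 cells with DMSO should lie nearer to the knockouts, and they did for 244 of the 553 shared genes measured in both arms (44.1%), 49.33% of the rises (44.29 to 54.38) and 33.33% of the falls (26.86 to 40.5). The arms were counted by different methods and the rises do not decide, so EV libraries that stand apart and an effect of the excisions cannot be told apart. A common cell lineage of S1KO and DKO stays open. DKO differed from S1KO at 233 genes and from S2KO at 631, but with only the groups compared this order turned. H2BC12 and ZNF804A were missing, at 3 counts or fewer, from S1KO and DKO as a pair. The pairs of S2KO with DKO and of S1KO with S2KO shared no such missing gene. A shared parent population and an effect of silencer 1 would both give a shared loss and fewer calls between S1KO and DKO, so they cannot be told apart.

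Single genes were picked because they departed most from the sum of the single treatments. Among the drugs RASD1 (log2 8.46), DEPP1 (4.44), HSPA1B (4.16) and RGS2 (4.13) stood above the sum. INPP1 (-4.46), PALD1 (-4.05), TMEM154 (-4) and TRIM67 (-3.99) stood below it. RASD1 had 1 and 2 counts with GSK343, so its fitted value is no bound, and it was 4.414 with unstranded counts. HSPA1B was at 2.122 without DMSO replicate 2 and was no longer called with any of 6 other libraries left out, nor TMEM154 with any of 4. Among the excisions 222 genes departed from the sum. S100A6 (10.45), ADAMTS9 (6.13), IL18R1 (6.13) and TSPAN5 (6.03) stood above it. EPSTI1 (-9.39), ZPLD1 (-7.74), SLC46A3 (-7.25) and CD96 (-6.94) stood below it. EPSTI1 and SLC46A3 in EV and S100A6 in S2KO had 2 or 3 counts in all, so their fitted values are no bounds and give no order. ADAMTS9 was at 1.507 with length-scaled TPM counts and was not called there. Of these 8 genes TSPAN5 and ZPLD1 alone kept their call with any library left out.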

How the results depend on the processing

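Counts of called genes depended on the library left out, the lone library then being assumed to vary like the other groups. They ran from 739 to 4287 for GSK343, 815 to 3121 for X5050, 4781 to 6889, 5830 to 8241 and 5780 to 8025 for both drugs at 72, 24 and 8 h, 5218 to 5624 and 3597 to 4907 for both drugs against GSK343 and X5050, 4178 to 4710 for 24 h against 8 h, 6288 to 7114 for 72 h against 24 h and 2296 to 4854 for the drug interaction. In the excision arm they ran from 249 to 446 for S1KO, 157 to 329 for S2KO, 526 to 1333 for DKO, 17 to 36 and 101 to 302 for DKO against S1KO and S2KO, and 33 to 155 for the interaction. Passing lists numbered 124 to 136 in the drug arm and 51 to 62 in the excision arm.

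With only the 72 h groups GSK343 gave 1542 genes and X5050 1313, and with only the groups compared 1118 and 617, and 2314 for the drug interaction. The share of rises among GSK343 calls went from 73.4% to 84.9% and 92.7%, and to 54.1% without DMSO replicate 1. Over all settings that made calls the share of rises ran from 41.7% to 57% for X5050, from 49.9% to 57%, 48.1% to 54% and 48.4% to 54.7% for both drugs at 72, 24 and 8 h, from 45.3% to 51.6% and 44.9% to 62.6% for both drugs against GSK343 and X5050, from 48.7% to 54.7% for 24 h against 8 h, 49% to 55.9% for 72 h against 24 h and 43.5% to 56.7% for the drug interaction. It ran from 59.2% to 76.7% for S1KO, 67.5% to 85.4% for S2KO, 52.6% to 74.1% for DKO, 16.7% to 63.5% and 43.4% to 59.6% for DKO against S1KO and S2KO and 23.5% to 36.8% for the interaction. With only the groups compared S1KO gave 300, S2KO 0 by edgeR, DKO against S1KO 562 and DKO against S2KO 312. Without the DKO libraries S1KO gave 358 and S2KO 160. DESeq2 gave 1654 for S1KO, 1082 for S2KO, 3112 for DKO, 848 and 1580 for DKO against S1KO and S2KO, and 741 for their interaction. Length-scaled TPM counts gave 143 and no filter 350 for DKO against S1KO. A replicate block gave 1348 for S1KO, 716 for S2KO, 3172 for DKO, 434 and 1286 for DKO against S1KO and S2KO, and 376 for the interaction. With the block the megakaryocytic list in DKO had a camera adjusted p of 0.0943, and HSPA1B in the drug interaction an edgeR adjusted p of 0.0753. Other DKO lists lost their call with it (above). The labels do not say whether equal replicate numbers pair the libraries. The deviations of equally numbered libraries correlated by 0.488, 0.622 and 0.566 among EV, S1KO and S2KO and by -0.0843 to -0.0591 with DKO. The cause was not tested.

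Camera with an estimated correlation passed 2 and 0 list tests (above). Mixed fry passed 280 in the drug arm and directional fry 27 in the excision arm. Shared calls of at least 1 log2 unit numbered 1174 for 24 h and 72 h, 1453 for 8 h and 24 h, 472 for GSK343 and both drugs, 153 for the single drugs, 481 for X5050 and both drugs, 236 for DKO and both drugs and 84 for S1KO and both drugs. By DESeq2 S1KO and DKO shared 1281, S1KO and S2KO 629, S2KO and DKO 805, DKO and both drugs 677 and S1KO and both drugs 295. ABCC3 turned from log2 1.45 ± 0.32 in DKO to -0.061 with length-scaled TPM counts.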

Other observations

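The neighbour test and the comparisons of replicates here were chosen after the results were seen. Genes that rose with GSK343 lay beside each other along the chromosomes. Of neighbouring pairs of tested genes 288 had both members higher, against a mean of 140.9 and a highest value of 178 in 1000 shuffled orders. The runs included SMOX, ADRA1D, PRNP, RASSF2 and SLC23A2, and ALX4, CD82, TSPAN18 and TP53I11. Pairs that overlap or share a name prefix were left out. The excess was not particular to GSK343 or to rises: all 12 such tests lay above the shuffled mean, with 92 pairs higher in DKO against 43.11 (highest 68) and 45 lower against 13.4 (highest 25). The cause was not tested.

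In DKO a run of FAS, LIPA, IFIT2, IFIT3 and IFIT1 rose together. With both drugs at 72 h the interleukin genes IL1A, IL1B, IL36RN and IL1RN did, and so did 7 pregnancy-specific glycoprotein genes from PSG3 to PSG9, near-identical copies whose single values are uncertain. Several of these genes were near 0 counts in the controls, so no fold is given.

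Replicates of the excision arm differed in nutrient response genes. The ATF4 targets were higher in replicate 2 of EV, S1KO, S2KO and, by little, DKO (values above). ASNS stood at 280.3 and 1410 CPM in EV and at 266 and 308 in DKO. Heat shock genes ran the other way (median log2 -0.92, -0.87, -1.21 and 0.05), as did globins (above).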
